A study of Homo sapiens with 4 samples.

How the data were processed

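PolyA RNA from SCC13 cells was sequenced from TruSeq libraries, per the labels' protocols, in 2 groups of 2 samples: cells infected with a lentivirus expressing a scrambled shRNA (control shRNA) and cells infected with one expressing an shRNA against CELF2 (CELF2 knockdown). The groups and the replicate numbers were taken from the sample titles. Whether the 2 knockdown samples carried the same shRNA sequence is not given in the sources used here.

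The authors deposited 1 table of raw read counts per Ensembl gene, with 1 column per library and 60617 genes. HISAT2, edgeR and the GRCh38 build are named in the submitters' processing notes, with no versions. The counting program, the gene annotation release, the strand setting and the treatment of reads shared between genes are not given in the sources used here. The deposited values are whole-number counts that sum to a different total in each library (27898889, 17649090, 19928788 and 23177056), and every row names a gene. Gene symbols were taken from the table, except for OAS1 and RPL6, 2 list members that the table gives under other symbols and that were matched by gene ID through a table of gene names after the data had been seen. Positions, gene types and transcript GC content came from GENCODE v29 (GRCh38), which held 58542 of the 60617 gene IDs and 15107 of the 15171 tested ones. Genes whose exons overlap those of another gene in GENCODE v29 have uncertain counts. Beside those marked as uncertain in the results, these are RRM2, UCA1, JUNB, MBNL1, TAGLN, SRSF1, HK2, HLA-B, SPARC, ESRP2, MT-ATP8, ICAM1, CELF1, CELF4, CELF5, CELF6, RPL23, RPS20, PMEL, MT-ND4, EEF1A1, OVOL1, ETV5 and DUSP6. The same holds for genes with near-identical copies, such as AKR1C1, HNRNPA1 and genes of histones and ribosomal proteins.

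Replicates were compared before they were used. The chi-square per degree of freedom between the 2 libraries of a group was 59.8 for the controls and 52.6 for the knockdown, so the replicates are distinct libraries. Across genes, the correlation of log2 CPM was 0.979 between the controls, 0.977 between the knockdown libraries and 0.953 to 0.971 between groups; genes are not independent replicates. The first principal component held 60.9% of the variance and separated the groups (-53.0 and -28.7 for the controls, 45.0 and 36.7 for the knockdown). Mitochondrially encoded genes took 5.07% and 5.74% of the counts in the controls and 5.80% and 4.19% in the knockdown.

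The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the deposited counts, with TMM normalization, the filterByExpr filter at its minimum count of 10, and Benjamini-Hochberg adjustment over all tested genes at 0.05; CELF2 was kept whatever its counts. The common biological coefficient of variation was 21.6%. CPM values are TMM-normalized, given as mean ± SD over 2 libraries, and standard errors of log2 fold changes come from the fit. Exact Poisson intervals (95%) and floors of 3 counts cover counting error only. Gene lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01 where at least 5 members were tested, with Benjamini-Hochberg adjustment over the 30 lists tested. Camera with an estimated correlation and fry were run beside it: 15 lists passed with the preset correlation and 0 with the estimated one (smallest adjusted p 0.402). Fry's directional test, which asks whether a list's genes move on balance in 1 direction, passed 0 lists (smallest adjusted p 0.165), and its mixed test, which asks whether they change in either direction, passed 6. Those 6 were stress keratins, epithelial junctions, immediate early genes, Notch, splicing factors and mitochondrially encoded genes. The S phase, mitosis and interferon lists did not pass fry's mixed test (adjusted p 0.113, 0.183 and 0.137). For each list the members past the threshold were also counted with p-values adjusted over the list alone.

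Before the data were examined, 33 gene lists, the tests, the alternatives and the rule for named genes were fixed. The lists covered S phase, G2 phase and mitosis, basal keratinocytes, keratinocyte differentiation, stress keratins, epithelial junctions, epithelial-mesenchymal transition, matrix proteases, interferon-stimulated genes, antigen presentation, NF-kB, p53, the unfolded protein response, cholesterol synthesis, hypoxia, NRF2, YAP, immediate early genes, Notch, MAPK feedback, EGFR and MET, WNT, stem cell markers, CELF and MBNL proteins, splicing factors, ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes, histones, and markers of fibroblasts, melanocytes, endothelial cells and immune cells. The rule named the CELF and MBNL members, the 12 genes with the largest log2 fold change per direction among those past the threshold with a mean of at least 5 CPM and separated libraries, up to 4 members per list with the smallest p, and the 5 most abundant genes. Some genes that the rule names are not reported here. UCA1, TIMP1, FAP, the CELF2 antisense genes and the cell type markers with 0 counts lie outside this rule and were chosen after their values were seen.

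The alternatives were DESeq2's size factors, upper-quartile factors and total counts in place of TMM, no filter on low counts, a filter of 1 CPM in 2 libraries, DESeq2 (1.42.0), limma-voom, edgeR's likelihood ratio test, a test against a 1.5-fold change (glmTreat), the replicate number as a block, and leaving out each library in turn, where the lone library of a group is assumed to vary like the other group. A correction for GC content, which removed a smooth trend of log2 CPM on transcript GC content from each library, was added after seeing the data. The main test, DESeq2, limma-voom, the likelihood ratio test, glmTreat, the replicate block, the GC correction, DESeq2's size factors and the leave-one-out fits were tested on simulated data drawn from the means and library sizes of this comparison, with 200 genes changed. With 14876 genes the main test recovered 32 of 100 genes changed 2-fold and 86 of 100 changed 4-fold with 6 false calls, DESeq2 recovered 47 and 91 with 17 false calls, the likelihood ratio test 49 and 92 with 29, limma-voom 31 and 86 with 7, and glmTreat 2 and 84 with 6. Without control replicate 1 the main test recovered 5 and 80 with 12 false calls, without control replicate 2 it recovered 17 and 85 with 23, and without knockdown replicate 1 or 2 it recovered 28 and 87 with 37, and 35 and 87 with 35. Of 2 changed and 20 unchanged lists of 20 genes in the same simulation, camera with its preset correlation called 2 and 0. With an estimated correlation camera called 0 and 0, so it missed both changed lists, and fry's directional test called 1 and 1. The simulated genes were drawn independently of each other, so the simulation does not test camera on correlated genes. In the data the estimated correlation was 0.980 for G2 phase and mitosis, 0.510 for S phase and 0.366 for interferon-stimulated genes.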

Results

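RNA sequencing of polyA RNA compared SCC13 cells carrying an shRNA against CELF2 with SCC13 cells carrying a scrambled control shRNA. SCC13 is a cell line from a human squamous cell carcinoma of the skin, and CELF2 is an RNA-binding protein of the CELF family that acts on the splicing, stability and translation of mRNAs. Each group had 2 libraries. The 2 control libraries held 27898889 and 17649090 counts, and the 2 knockdown libraries 19928788 and 23177056 counts. A floor of 3 counts corresponded to 0.108 and 0.170 CPM (counts scaled to the depth of the library) in the control libraries and to 0.151 and 0.129 CPM in the knockdown libraries. Between 20733 and 22041 genes had at least 1 count in a library. The labels do not state that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

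The targeted gene was almost absent from the counts of all 4 libraries. CELF2 (ENSG00000048740, GRCh38 chromosome 10, 10798397 to 11336675, plus strand, protein coding in GENCODE v29) had 1 count in control replicate 1 and 0 counts in control replicate 2 and in each knockdown library. The exact Poisson 95% upper bound was 0.122 CPM over the 2 control libraries together and 0.0856 CPM over the 2 knockdown libraries together. These bounds cover counting error only. A loss of CELF2 mRNA was therefore not detectable at this depth, no fold change is given for it, and the counts of the target do not check which libraries carry the knockdown. The antisense genes CELF2-AS1 and CELF2-AS2 had 0 counts in every library.

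Of the related RNA-binding proteins, CELF1, MBNL1, MBNL2 and MBNL3 were well counted. CELF1 had a mean of 149 CPM in the controls and 130 CPM in the knockdown (log2 fold change -0.19 ± 0.18, SE). MBNL1, a splicing regulator that often acts against CELF proteins, went from 125 ± 30.3 CPM (SD, n = 2) to 57.2 ± 0.860 CPM (n = 2), a log2 fold change of -1.13 ± 0.21 that did not pass over all genes (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0533). MBNL2 had a log2 fold change of 0.69 ± 0.21 and MBNL3 of -0.36 ± 0.26, and neither passed. CELF5 was near the floor, with 3 and 2 counts in the controls and 14 and 13 in the knockdown. CELF4 had 1 and 0 counts in the controls and 1 and 0 in the knockdown, and CELF3 and CELF6 had 0 counts everywhere. Over all genes, 0 of the 6 tested members of the CELF and MBNL list, CELF2 among them, changed (edgeR quasi-likelihood test), and adjusted over the list alone 2 rose (CELF5 and MBNL2) and 1 fell (MBNL1). Together these 6 genes did not stand apart from other genes (camera, Benjamini-Hochberg adjusted p = 0.680).

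The comparison asks which transcripts differ between CELF2 knockdown and control cells. Genes of mitosis and of DNA replication were lower in the knockdown (median log2 fold changes of -1.44 over 19 genes and -1.02 over 22), and MKI67, RRM2 and CDC20 fell 3.36-fold to 4.29-fold. Interferon-stimulated genes were higher (median 1.31 over 24 genes, and 0.69 without knockdown replicate 2), and MX1, OAS1, IFI6 and IFIT1 rose 2.64-fold to 3.38-fold. These 3 lists stood apart from other genes by camera with its preset correlation (largest Benjamini-Hochberg adjusted p = 8.60e-13). They did not with an estimated one (camera, adjusted p = 0.402 for each). The estimated correlation was 0.980 for mitosis, 0.510 for DNA replication and 0.366 for interferon-stimulated genes, well above the preset one. The small p-values with the preset correlation are therefore not read as strong evidence. The unfolded protein response list, with an estimated correlation of 0.859, even turned with the control left out (medians -0.54 without replicate 1 and 1.23 without replicate 2). Other genes that rose included NOTCH3 (3.39-fold), WNT10A (7.39-fold) and SERPINB3 (18.2-fold).

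At an adjusted p below 0.05, 133 of 15171 tested genes changed, 92 higher and 41 lower in the knockdown (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). In each of the 133 the knockdown libraries lay on 1 side of both control libraries, as did 54.9% of all tested genes against 33.3% by chance. At an unadjusted p below 0.05 there were 3347 genes, where chance alone gives 759. Genes are not independent replicates, and the first principal component held 60.9% of the variance. Any broad difference between these 4 libraries could give such excesses over chance, so they are no separate evidence of a knockdown effect. The calls sat close to the threshold: 131 of the 133 had an adjusted p above 0.04, and the smallest, 0.0323, was that of CYP1B1 and UCA1. UCA1, a long noncoding RNA chosen here after its values were seen, rose from 19.5 ± 0.117 to 91.1 ± 8.14 CPM (SD, n = 2 each). Without control replicate 1 the test called 0 genes (smallest adjusted p 0.0955, 1724 genes at an unadjusted p below 0.05), and without knockdown replicate 2 it called 7, all higher. Without control replicate 2 it called 616 genes and without knockdown replicate 1 it called 368; limma-voom called 0 genes and DESeq2 called 1386. Of the 133 genes 69.2% were higher; after a correction for GC content, chosen after seeing the data, 50.2% of 323 called genes were higher.

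The 12 largest increases among genes with a mean of at least 5 CPM ran from a log2 fold change of 2.54 to 3.85. OLR1, which encodes a receptor for oxidized low-density lipoprotein, rose from 1.29 ± 0.107 to 18.6 ± 10.2 CPM (SD, n = 2 each), a log2 fold change of 3.85 ± 0.46 (SE). TP53INP1, a stress protein that takes part in autophagy and is induced by p53, rose from 1.06 ± 0.0903 to 11.1 ± 4.72 CPM. IFITM1, an interferon-induced membrane protein, rose from 2.86 ± 0.499 to 23.5 ± 13.98 CPM. WNT10A, a secreted WNT ligand, rose from 10.1 ± 1.22 to 74.7 ± 53.1 CPM, with 112 and 37.2 CPM in the 2 knockdown libraries. INHBB, a subunit of activins and inhibins, rose from 2.15 ± 0.568 to 15.4 ± 1.10 CPM. CYP1B1, a cytochrome P450 enzyme induced through the aryl hydrocarbon receptor, rose from 8.89 ± 0.221 to 59.9 ± 14.2 CPM. MMP28, a secreted metalloproteinase, rose 6.63-fold, and ALPP, the placental alkaline phosphatase, rose 6.27-fold. The other 4 were SLC17A7 (a vesicular glutamate transporter, log2 fold change 2.78), FAM83E (2.54), BAIAP3 (2.54) and the long noncoding RNA AL590004.3 (3.47). The adjusted p was 0.0323 for CYP1B1, 0.0491 for WNT10A and 0.0483 for each of the other 10 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). The counts of IFITM1 (exons shared with IFITM2), CYP1B1 (RMDN2 and CYP1B1-AS1), ALPP (close paralogs) and BAIAP3 (TSR3) are uncertain, since the strand setting and the treatment of shared reads are not given in the sources used here.

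The 12 largest decreases ran from a log2 fold change of -2.39 to -1.75. MKI67, the Ki-67 marker of proliferating cells, fell from 447 ± 196 to 104 ± 32.6 CPM (SD, n = 2 each), a log2 fold change of -2.10 ± 0.34 (SE). RRM2, the regulatory subunit of ribonucleotide reductase, fell from 270 ± 68.9 to 66.0 ± 12.99 CPM. CDC20, an activator of the anaphase-promoting complex, fell from 381 ± 129 to 113 ± 30.5 CPM. HMMR, a hyaluronan receptor that also binds the mitotic spindle, fell from 49.1 ± 20.7 to 10.7 ± 2.37 CPM, and DEPDC1B from 47.1 ± 22.7 to 9.02 ± 1.24 CPM. LMNB1, which encodes lamin B1 of the nuclear envelope, fell from 122 ± 55.5 to 31.2 ± 5.73 CPM. SPDL1, which brings dynein to kinetochores, had a log2 fold change of -1.87, and FAM111B, CDCA3, IQGAP3 and SAPCD2 had -2.29, -1.98, -1.89 and -1.79. MT-ND6, the mitochondrial mRNA read from the opposite strand to the others, fell from 113 ± 35.3 to 29.7 ± 7.44 CPM. Each of the 12 had an adjusted p of 0.0483 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Control replicate 1 held the highest value of each of these 12 genes; MKI67 stood at 585 CPM there and at 308 CPM in control replicate 2. HMMR, CDCA3 and SAPCD2 share exon positions with genes on the opposite strand, and MT-ND6 lies within the transcribed region of the other mitochondrial strand, so their counts are uncertain.

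**Figure D1:**
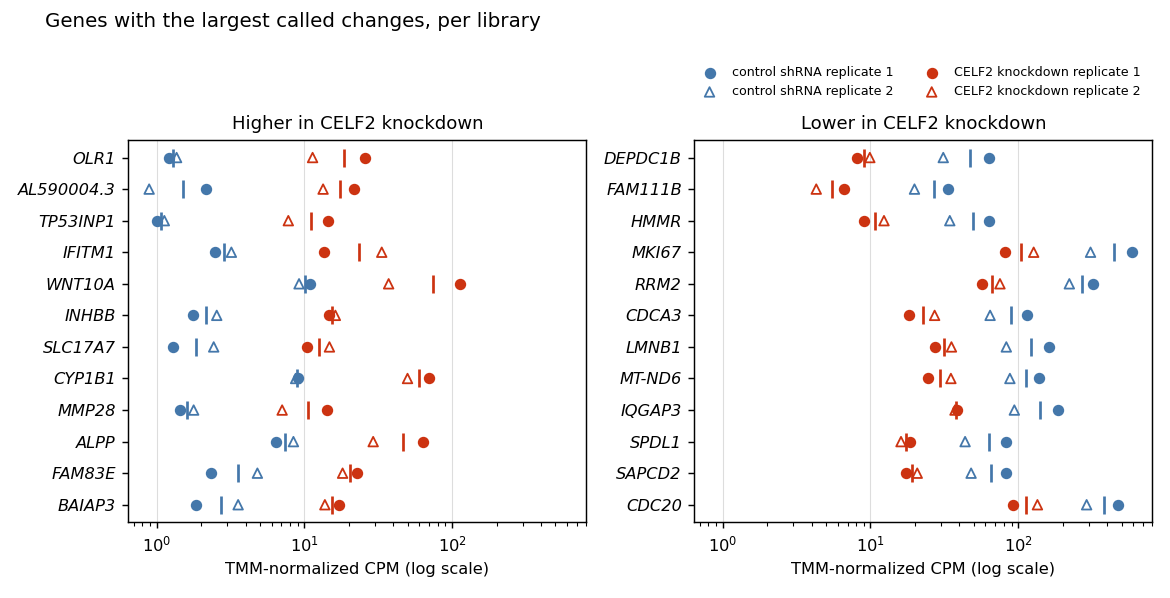
TMM-normalized CPM (log axis) of the 12 genes with the largest called increases and the 12 with the largest called decreases among genes with a mean of at least 5 CPM, with 1 point per library and a vertical bar at each group's mean (n = 2). In each of these genes both knockdown libraries lie on the same side of both control libraries, and WNT10A has the widest gap between its knockdown libraries (112 and 37.2 CPM).

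Among the gene lists, the 2 cell cycle lists had the lowest medians. Of 19 tested genes of G2 phase and mitosis, 2 fell (MKI67 and CDC20) and 17 did not pass over all genes, while adjusted over the list alone 19 fell; the median log2 fold change was -1.44. AURKB, a kinase of chromosome segregation, and UBE2C, a ubiquitin-conjugating enzyme of mitosis, had log2 fold changes of -1.39 and -1.44. Of 22 tested genes of S phase and DNA replication, 4 fell (RRM2, TYMS, CDC45 and MCM5) and 18 did not pass, while adjusted over the list alone 20 fell and 1 rose, with a median of -1.02. CDC45 and MCM5, parts of the replicative helicase, fell by 1.44 and 1.06 on the log2 scale, and TYMS, thymidylate synthase, by 1.59; TYMS shares exon positions with ENOSF1 and is uncertain. Both lists were lower than other genes (camera with its preset correlation, Benjamini-Hochberg adjusted p = 1.23e-23 and 9.43e-22), a call lost with an estimated correlation (adjusted p = 0.402 for each with an estimated correlation). Without control replicate 1 the medians were -1.04 and -0.83.

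Of 30 tested splicing factors, 0 changed over all genes (edgeR quasi-likelihood test), and adjusted over the list alone 19 fell, with a median log2 fold change of -0.61 and 29 of the 30 below 0. HNRNPA1, an abundant hnRNP protein, had a log2 fold change of -0.96 ± 0.18 (SE), and the SR proteins SRSF1, SRSF3 and SRSF7 had -1.07, -0.86 and -0.88. The list was lower than other genes (camera, Benjamini-Hochberg adjusted p = 4.42e-11; adjusted p = 0.402 with an estimated correlation). In 13 mitochondrially encoded genes 1 fell (MT-ND6) and 12 did not pass, and adjusted over the list alone 2 fell (MT-ND6 and MT-ATP8), with a median of -0.28 (camera adjusted p = 0.00561; adjusted p = 0.624 with an estimated correlation). Of 42 cytosolic ribosomal protein genes 0 changed over all genes and 0 adjusted over the list alone, with a median of -0.18; RPL23 had -0.56 and RPS20 -0.49 (camera adjusted p = 0.0171; adjusted p = 0.755 with an estimated correlation). The mitochondrial list no longer passed without knockdown replicate 2 (camera adjusted p = 0.184), and the ribosomal list without control replicate 2 (0.438) or knockdown replicate 2 (0.0834). The mitochondrial median was -0.46 without control replicate 1, -0.16 without control replicate 2, -0.54 without knockdown replicate 1 and -0.14 without knockdown replicate 2; the ribosomal median was -0.27 without control replicate 1 and -0.043 without control replicate 2.

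With all 4 libraries the interferon-stimulated genes had the highest median of the lists tested, 1.31. Without control replicate 2 the NF-kB and stress keratin medians were higher (1.43 and 1.37 against 1.30). Without knockdown replicate 2 the stress keratin and fibroblast marker medians were higher (0.96 and 0.77 against 0.69). Of the 24 tested interferon-stimulated genes, 4 rose over all genes, and adjusted over the list alone 17 rose and 0 fell. MX1, an antiviral GTPase, rose from 7.05 ± 0.806 to 23.9 ± 5.46 CPM (SD, n = 2 each), IFI6 from 12.1 ± 1.29 to 35.5 ± 9.42 CPM, and IFIT1, which binds viral RNA, from 20.1 ± 3.36 to 53.05 ± 10.7 CPM. OAS1, an enzyme activated by double-stranded RNA that the deposited table lists under another symbol, rose from 10.6 ± 2.45 to 34.4 ± 2.22 CPM. The exons of MX1 and OAS1 overlap those of another gene on the opposite strand, so their counts are uncertain. The list was higher than other genes (camera, Benjamini-Hochberg adjusted p = 8.60e-13; adjusted p = 0.402 with an estimated correlation). Its median was 0.69 without knockdown replicate 2, where camera still called it (adjusted p = 2.33e-06).

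Of 12 tested stress keratins and antimicrobial proteins, 1 rose, and adjusted over the list alone 5 rose, with a median of 1.00. SERPINB3, a squamous cell carcinoma antigen, rose from 0.429 ± 0.102 to 8.06 ± 1.41 CPM (SD, n = 2 each), although reads shared with its near-identical neighbor SERPINB4 make both uncertain. S100A9, a calcium-binding protein of inflamed epidermis, and SLPI, a secreted protease inhibitor, had log2 fold changes of 1.10 and 1.11 without passing over all genes. The list was higher than other genes (camera, Benjamini-Hochberg adjusted p = 1.37e-07; adjusted p = 0.402 with an estimated correlation). Of 15 matrix protease and plasminogen system genes 1 rose (MMP28), and adjusted over the list alone 6 rose, among them the inhibitors TIMP3 (log2 fold change 2.43) and TIMP1 as well as MMP14 (0.65); the median was 0.65 (camera adjusted p = 1.66e-04; adjusted p = 0.402 with an estimated correlation). The median of this list was 1.11 without control replicate 2.

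In the Notch pathway 1 of 16 genes rose, and adjusted over the list alone 6 rose, with a median of 0.34. The receptor NOTCH3 rose from 11.2 ± 1.92 to 38.01 ± 1.88 CPM (SD, n = 2 each), and HES1, a transcriptional repressor induced by Notch, had a log2 fold change of 1.05 (camera, Benjamini-Hochberg adjusted p = 0.00315; adjusted p = 0.402 with an estimated correlation). In the WNT pathway 1 of 18 genes rose (WNT10A), and adjusted over the list alone 4 rose, with a median of 0.34; LGR6, a receptor for R-spondins, had a log2 fold change of 2.31 from 0.625 CPM in the controls (camera adjusted p = 0.0168; adjusted p = 0.402 with an estimated correlation). The Notch median was 0.81 without control replicate 2, 0.54 without knockdown replicate 2, 0.55 with no filter on low counts and 0.17 after the GC correction, and the WNT median was 0.15 without control replicate 1. Camera still called the list in question in each of those fits (largest adjusted p = 0.0253 for Notch).

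Another 5 lists passed camera with higher values although 0 of their members changed over all genes (edgeR quasi-likelihood test). Cholesterol synthesis (21 genes, median 0.48) included MSMO1 (0.98), and adjusted over the list alone 0 changed (camera, Benjamini-Hochberg adjusted p = 1.14e-04; adjusted p = 0.624 with an estimated correlation). Immediate early genes (16 genes, median 0.40) included the AP-1 subunits JUNB (1.36) and JUND (0.90), and adjusted over the list alone 3 rose (camera adjusted p = 0.00160; adjusted p = 0.402 with an estimated correlation). NF-kB and inflammatory cytokine genes (16 genes, median 0.79) included IL1B (1.48) and ICAM1 (1.30), and adjusted over the list alone 3 rose (camera adjusted p = 0.0168; adjusted p = 0.624 with an estimated correlation). NRF2 targets (14 genes, median 0.51) included AKR1C1 (2.57) and heme oxygenase HMOX1 (1.35), and adjusted over the list alone 5 rose (camera adjusted p = 0.0207; adjusted p = 0.624 with an estimated correlation). Antigen presentation and checkpoint ligands (15 genes, median 0.17) included HLA-B (0.90) and TAPBP (0.86), and adjusted over the list alone 2 rose (camera adjusted p = 0.0303; adjusted p = 0.624 with an estimated correlation). Without knockdown replicate 2 the immediate early (camera adjusted p = 0.0596), NF-kB (0.340) and antigen presentation (0.162) lists no longer passed. The same held without control replicate 1 for NF-kB (0.964), NRF2 (0.103) and antigen presentation (0.317), without knockdown replicate 1 for NRF2 (0.0684), and after the GC correction for antigen presentation (0.0623). The cholesterol median was 0.28 and the immediate early median 0.73 without control replicate 1. The NF-kB median was 0.46 and 1.43 without control replicate 1 and 2, and 0.10 without knockdown replicate 2. The NRF2 median was 0.19 without knockdown replicate 1. The antigen presentation median was 0.30 and 0.54 without control replicate 1 and 2, and 0.37 and 0.35 without knockdown replicate 1 and 2.

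**Figure D2:**
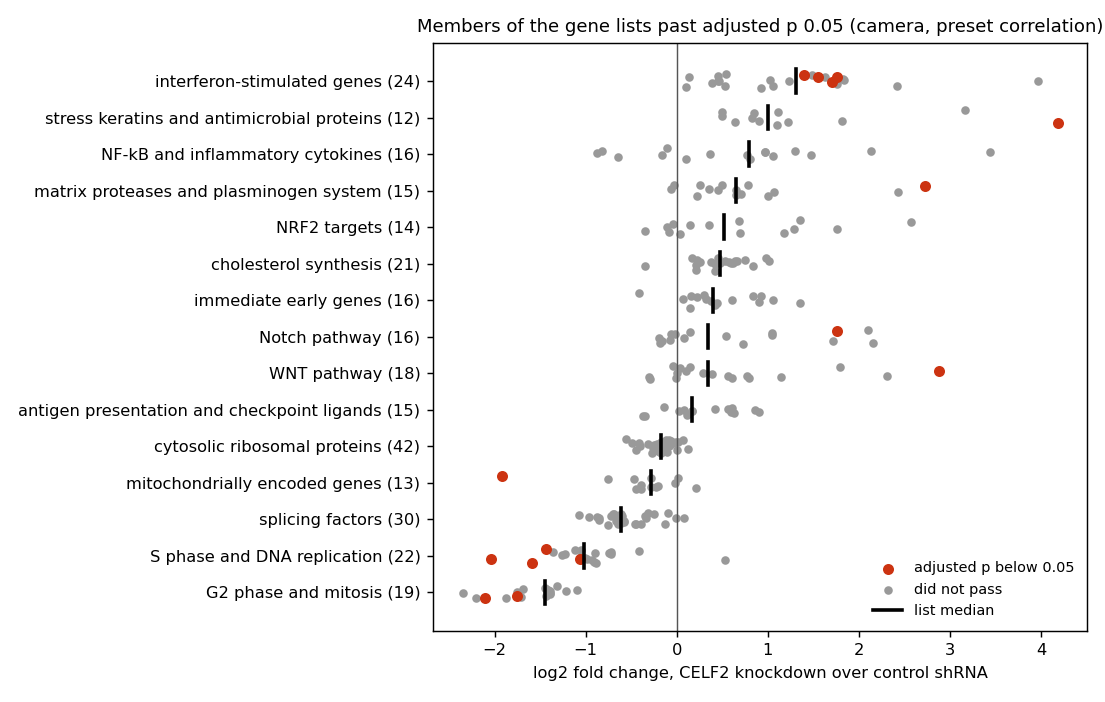
Log2 fold change, CELF2 knockdown over control shRNA, of each tested member of the 15 gene lists past an adjusted p of 0.05 by camera with its preset correlation, with 1 point per gene, red points for genes past an adjusted p of 0.05 in the edgeR quasi-likelihood test, and a black bar at each list's median. The number of tested members follows each list's name, and the medians run from -1.44 for G2 phase and mitosis to 1.31 for interferon-stimulated genes; the calls of these lists were lost with an estimated correlation (smallest adjusted p 0.402).

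The other 15 tested lists did not pass camera, and 0 of their members changed over all genes (edgeR quasi-likelihood test). Epithelial junctions (22 genes, camera Benjamini-Hochberg adjusted p = 0.220) moved apart: adjusted over the list alone 4 rose and 2 fell, with CLDN1 (2.54) and CLDN4 (1.80) of tight junctions and the desmosomal cadherin DSG3 (1.04) above 0, and the epithelial splicing regulator ESRP2 (-0.77) below. In epithelial-mesenchymal transition (13 genes, 0.572), adjusted over the list alone 1 rose (SNAI2, 0.90) and 2 fell (TAGLN, -1.58, and SPARC, -0.77). In p53 targets (16 genes, median 0.27, 0.164) 1 rose adjusted over the list alone (BTG2, 0.98), and in hypoxia and glycolysis (21 genes, 0.584) 1 fell (hexokinase HK2, from 119 to 59.2 CPM). Adjusted over the list alone 0 genes changed in the keratinocyte differentiation (11 genes, median 0.87, camera adjusted p = 0.251), basal keratinocyte (14 genes, 0.34, 0.220), YAP target (13 genes, 0.20, 0.220), EGFR and MET (13 genes, 0.20, 0.220), MAPK feedback (15 genes, -0.05, 0.606), stem cell marker (9 genes, 0.03, 0.602), oxidative phosphorylation (28 genes, -0.06, 0.305), replication-dependent histone (8 genes, 0.27, 0.875), fibroblast marker (5 genes, 0.54, 0.220) and unfolded protein response lists (18 genes, 0.06, 0.439). Leaving out 1 library brought some of these past camera's threshold: differentiation without knockdown replicate 1 (adjusted p = 0.00285), basal keratinocyte (0.00160) and p53 targets (0.00897) without control replicate 2, fibroblast markers without knockdown replicate 2 (0.0452), and MAPK feedback, with lower values, without control replicate 1 (0.00827) or knockdown replicate 2 (0.00543). Medians also moved with the library left out. The differentiation median was -0.22 without knockdown replicate 2, the p53 median 0.038 without control replicate 1 and 0.12 without knockdown replicate 2, and the basal keratinocyte median 0.18 without control replicate 1 and 0.14 without knockdown replicate 1. The MAPK feedback median was 0.37 and the histone median -0.29 without control replicate 2, and without knockdown replicate 2 these were -0.51 and -0.46. Of 15 listed histone genes 8 were tested in this polyA RNA. The 4 with the smallest p had control means of only 0.327 to 1.27 CPM, so the histone median rests partly on low counts. The MAPK feedback median was also -0.39 without control replicate 1 and 0.20 without knockdown replicate 1. The EGFR and MET median was 0.037 and 0.42 without control replicate 1 and 2, and 0.32 and 0.10 without knockdown replicate 1 and 2. The stem cell median was 0.37 and -0.036 without control replicate 1 and 2, and 0.0048 and 0.11 without knockdown replicate 1 and 2. The fibroblast median was 0.26 without knockdown replicate 1, and the YAP median was 0.33 without control replicate 2. The oxidative phosphorylation median was -0.11 and 0.017 without control replicate 1 and 2, and -0.13 without knockdown replicate 2.

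Of the markers of other cell types, some were not counted in any library and others were well counted. The leukocyte gene PTPRC and the fibroblast genes COL1A2, COL3A1, DCN and LUM had 0 counts everywhere, as did the melanocyte genes MLANA and TYR. Other fibroblast markers, which tumor cells can also express, were well counted in each library. COL5A1 had 807 and 1042 counts in the controls and 823 and 834 in the knockdown, FBLN1 had 819 and 427 against 947 and 775, and FAP had 667 and 314 against 554 and 379. COL1A1 had 366 and 271 counts in the controls and 760 and 491 in the knockdown (14.6 and 29.1 CPM), without passing (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.122). The immune, melanocyte and endothelial lists had 2, 2 and 1 tested members, too few for camera, and 0 of these genes changed over all genes (edgeR quasi-likelihood test). CD14, a co-receptor for lipopolysaccharide, had 34 and 6 counts in the controls and 216 and 48 in the knockdown and rose adjusted over the list alone. VWF, the only tested endothelial gene, had 0 and 0 counts in the controls and 10 and 14 in the knockdown. It passed the count filter through the knockdown libraries alone. With 1 tested member the list gives no adjustment (edgeR quasi-likelihood test, unadjusted p = 0.00157), so no rise of VWF is read from it. CSF1R, a macrophage growth factor receptor, had 277 and 89 counts in the controls and 282 and 164 in the knockdown, and with PMEL and MITF it did not pass on either scale. The 5 most abundant genes, FN1, MT-CO1, EEF1A1, MT-ND4 and MT-RNR2, had log2 fold changes between -0.28 and 0.32 and did not pass.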

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

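The GC correction was chosen after the data were seen, and the other settings before the data were examined. The 133 genes kept their direction in all 15 alternative fits. In each of the 133 both knockdown libraries lay on 1 side of both control libraries, so leaving out 1 library could hardly turn it. The other fits used the same libraries, so the kept direction is no separate support. The count of calls differed from 133 in each of the 15 fits. It was 211 with DESeq2's size factors (133 higher, 78 lower), 225 with upper-quartile factors (163 and 62), 416 with total counts (306 and 110), 2139 with no filter (1343 and 796), 173 with a filter of 1 CPM in 2 libraries, 1386 with DESeq2 (772 and 614), 1605 with the likelihood ratio test (941 and 664) and 323 with the GC correction (162 and 161). Of the 133, 132 were called with the GC correction and 133 in each of the other fits just named. Limma-voom called 0 genes, 0 higher and 0 lower (smallest adjusted p 0.0560, 3404 at an unadjusted p below 0.05), and so did glmTreat at 1.5-fold (0.0526, 1484). Leaving out 1 library gave 0 to 616 genes, 0 to 346 higher and 0 to 270 lower; 126 of the 133 were kept without control replicate 2, 128 without knockdown replicate 1, 7 without knockdown replicate 2 and 0 without control replicate 1. The cause of these shifts was not tested. Leaving out 1 library costs degrees of freedom, and the count rose without some libraries and fell without others. The simulated data also gave different results by the library left out. There 5 to 35 of 100 genes changed 2-fold were recovered, against 32 in the main test, with 12 to 37 false calls against 6. The direction of the shifts therefore cannot tell lost degrees of freedom from differences between libraries. The labels do not say whether the replicate numbers mark a batch or a pairing, and the main test does not use them. In the numbering of the column names the same-numbered libraries follow each other. With the replicate block 1579 genes were called (952 higher, 627 lower). The simulated data held no replicate effect. There the block gave 41 false calls, the main test 6 and the likelihood ratio test 29. Over 11248 genes the deviations of same-numbered libraries had r = 0.176, from 2 pairs. The second principal component (24.5% of the variance) parts the numbers: 21.8 and 30.9 for the libraries numbered 1, -26.0 and -26.7 for those numbered 2. With the block 2 more lists passed camera, basal keratinocyte (Benjamini-Hochberg adjusted p = 0.0383) and keratinocyte differentiation (0.0444), and no list was lost. Camera with its preset correlation called 12 to 17 lists in every fit it was run on. With an estimated correlation, and with fry's directional test, 0 lists passed, while fry's mixed test passed 6. List tests were not made for the likelihood ratio test and glmTreat, which camera does not use, and CELF2 has no fold change in any setting because both groups lie under the floor.

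Of 149 named genes, 33 passed the threshold and 0 of these reversed, which their separated libraries made almost certain. Another 13, none past the threshold, reversed when 1 library was left out, with log2 fold changes from -0.22 to 1.78 for OVOL1, -0.72 to 2.27 for ATF3, -1.93 to 1.41 for HERPUD1, -1.23 to 0.064 for ETV5, -1.04 to 0.24 for DUSP6 (0.069 without knockdown replicate 1), -0.065 to 0.66 for ABCG2, -0.13 to 1.59 for HIST1H2BK, -0.72 to 0.41 for COL5A1, -0.27 to 0.39 for MITF, -0.13 to 0.97 for CSF1R, -0.22 to 0.72 for FN1, -0.066 to 0.17 for EEF1A1 (-0.047 without knockdown replicate 1) and -0.12 to 0.63 for MT-RNR2; the cause was not tested.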

Other observations

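The look at the unfolded protein response list, the GC correction and the tests of CELF2 mRNA loss, of reads lost to overlapping genes and of depth were chosen after the data were seen. Of the 30 tested lists, the one whose mean differed most between the 2 control libraries was that of the unfolded protein and integrated stress response, a program that cells turn on when proteins misfold in the endoplasmic reticulum. HERPUD1, which takes part in the degradation of such proteins, stood at 65.7 CPM in control replicate 1 and 654 CPM in control replicate 2, and at 127 and 218 CPM in the 2 knockdown libraries. Averaged over the 18 tested members, centred log2 CPM was -1.05 and 0.77 in the controls and -0.18 and 0.46 in the knockdown libraries. The list's median log2 fold change was 0.06 with all libraries and turned with the control used. It was -0.54 without control replicate 1 (camera, Benjamini-Hochberg adjusted p = 2.11e-07) and 1.23 without control replicate 2 (adjusted p = 1.00e-11), it also passed with higher values without knockdown replicate 1 (0.0279), and with all 4 libraries it did not pass (0.439; adjusted p = 0.881 with an estimated correlation). No direction of this program between knockdown and control can be read from these libraries.

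The lower genes of DNA replication and mitosis were set against a GC content trend and against control replicate 1, the library with the highest values of these genes. Over the 41 members of both lists the median log2 fold change was -1.32, and it was -1.19 after the GC correction and -0.93 without control replicate 1, with upper quartiles of -1.05 and -0.76, which argues against either as the whole cause. Averaged over the mitosis members, centred log2 CPM was 1.26 and 0.29 in the controls and -1.02 and -0.53 in the knockdown. There the controls lay further apart than control replicate 2 and knockdown replicate 2. For DNA replication the averages were 0.64 and 0.35 in the controls and -0.62 and -0.37 in the knockdown. The size of the mitosis decrease thus depends on the control library used. A loss of CELF2 mRNA as the cause cannot be told from other differences between the cultures, because CELF2 had 1 count in the 2 control libraries together. Cell density and culture time, which the labels do not give, were not tested and stay open. A response to the shRNA or to the dose of virus, without any role of CELF2, was not tested either and stays open.

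The higher interferon-stimulated genes had a median log2 fold change of 1.31 over 24 members. The median was 1.41 after the GC correction and 1.11 without control replicate 1, with lower quartiles of 0.51 and 0.49, which argues against both as the whole cause. Without knockdown replicate 2 the median was 0.69, and averaged over the members centred log2 CPM was 0.25 and 0.92 in the 2 knockdown libraries. Immune cells in the knockdown cultures are excluded as a source by the leukocyte gene PTPRC, whose largest count in the knockdown libraries was 0, and the macrophage gene CD163 also had 0 counts; CD14 (34 and 6 counts in the controls, 216 and 48 in the knockdown) and CSF1R (277 and 89, 282 and 164) were counted without them. A response to the shRNA or to the dose of virus, which could raise these genes without any role of CELF2, was not tested and stays open beside an effect of the knockdown.

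The near absence of CELF2 from the control libraries was set against depth and overlapping genes. In the shallower control library 3 counts correspond to 0.170 CPM, so depth is excluded as the reason why a gene at 1 CPM would go unseen; a CELF2 level below that floor stays possible. Reads lost to overlapping genes cannot be told apart from a low level: GENCODE v29 has 0 genes with exons over those of CELF2, but 2075 gene IDs of the table lie outside that release. A low level of CELF2 mRNA in SCC13 cells stays open and was not tested by another method here.

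CELF proteins bind GU-rich elements in 3' UTRs and can destabilize the mRNAs that carry them, so a hypothesis was that such mRNAs rise in the knockdown. Of 12675 tested genes with an annotated 3' UTR, 282 held the element TGTTTGTTTGT. Their median log2 fold change was -0.03, at percentile 54.05 of 10000 lists of genes without it matched on 3' UTR length, 3' UTR GC content and mean expression (median -0.03, 95% of lists between -0.09 and 0.02), so the prediction was not met. In simulations on these genes a shift of 0.1 lay above that range of matched lists in 88 of 100 draws, a shift of 0.2 in 100 and no shift in 5, so a smaller shift could have been missed. With 1 CELF2 count in the 2 control libraries together, no loss of CELF2 mRNA was visible. The test therefore cannot show whether CELF2 acts on such mRNAs. CELF1, another CELF protein, had means of 149 CPM in the controls and 130 CPM in the knockdown.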
